A study of Homo sapiens with 16 samples.

How the data were processed

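LNCaP cells, an androgen-responsive human prostate cancer line, were grown in RPMI with 10% FBS and transfected with siRNA 24 h after plating. RNA was taken 48 h after transfection with an RNeasy kit, and polyA RNA was sequenced on an Illumina instrument. The 16 libraries form 4 groups of 4 replicates: a control siRNA (siNT) and siRNAs against GATA2, HOXB13 and TFAP2C. All 16 were used and no column was left out. The labels do not say whether replicates are separate cultures, so the p-values measure spread between these samples, which may be technical. The siRNA sequences, and whether each target was met by a single siRNA or a pool, are not given in the sources used here.

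The starting point was the deposited table of 20111 gene symbols. Per the submitters' processing notes, reads were aligned with STAR to hg19 and expression was estimated with Cufflinks; versions are not given in the sources used here. The deposited values are called counts by the authors but proved to be FPKM: they are not whole numbers, and low values multiplied by transcript length cluster at one step and its double. The test fixed for that case was therefore used in place of a count model. A spacing of this kind in 5266 genes with a single transcript also gave an approximate number of fragments per library. Raw reads were not analysed here. Names were matched to GENCODE 29, which is on GRCh38 and served only for gene names, transcript lengths and 3′ UTR sequence; no coordinates are reported.

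A gene was tested when it had at least 1 FPKM in at least 4 libraries; 11111 genes did and 9000 did not. Values were taken as log2(FPKM + 1) and fitted in a single limma model with a robust mean-variance trend over the 16 libraries (R 4.3.3, limma 3.58.1). Each knockdown was compared with siNT, and the knockdowns with each other. A gene changed when its Benjamini-Hochberg adjusted p was under 0.05. Fold changes are differences of group means on the log2(FPKM + 1) scale, which understates changes of genes at low values. Adjusted p-values of single genes are from limma. Group values are mean ± SD in FPKM with n = 4.

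In total, 25 gene lists were written from general knowledge, and the 21 with at least 3 tested genes were tested with camera (limma) at its preset correlation of 0.01. Their p-values were adjusted over all lists and the 3 knockdowns. Beside each list call stands camera with the correlation estimated from the data, and the number of members past the threshold when p-values are adjusted over the list alone. The lists are androgen-induced genes, androgen-repressed genes, luminal transcription factors, HOXB and PRAC genes, the GATA and AP-2 families, and AP-2γ targets known from other cells. They go on with cell cycle, p53 targets, interferon, integrated stress and unfolded protein response, cholesterol and fatty acid synthesis, steroid metabolism and glucuronidation, luminal markers, mesenchymal genes, hypoxia and MHC class I. The remaining ones are mitochondrially encoded genes, cytosolic ribosomal proteins, metallothioneins, housekeeping genes, and neuroendocrine, basal, fibroblast and immune markers. Of 458 symbols, 454 were found as written, 2 under another symbol and 2 were not matched.

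Genes were named by a rule. It takes the 3 targets, then KLK3, KLK2, TMPRSS2 and FKBP5, and up to 4 members of each list with the smallest adjusted p. It also takes the 8 largest rises and 8 largest falls per knockdown among changed genes with a mean of at least 5 FPKM in the higher group. For those picks the 4 libraries had to lie on one side of the 4 controls, and non-coding or pseudogene-like names were left out. For shared responses it takes 6 genes moving one way in all 3 knockdowns and 6 moving opposite ways. For each pair of knockdowns it takes the 5 largest differences in each direction. Some genes the rule takes, and 1 of the lists, are not reported here. The groups, the test, the filter, the lists, this rule and most alternatives were fixed before the data were examined. Genes that share sequence with close relatives (UGT2B, KLK2 and KLK3, ribosomal protein, histone, TMSB4X and HLA genes) are reported as uncertain, because reads may be assigned between them.

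Words of 7 bases in 3′ UTRs were scored in 10091 tested genes, 90.8% of the total, with a UTR of at least 50 bases. For each of 16088 words found in at least 50 genes, a t statistic compared log2 fold changes of genes with and without the word, adjusting for UTR length and base content. The lowest and highest t of 100 permutations of the fold changes set the limits. The pipeline was tested on simulated data made from these 11111 genes, with 50 genes changed at each fold. The changed genes were drawn only from genes with higher control values, so recovery of genes at low values was not tested. Noise was drawn independently, without correlation between genes or differences shared by replicate number. At 1.5-fold the pipeline recovered 80%, 92% and 88% of the changed genes in siGATA2, siHOXB13 and siTFAP2C, and at 1.2-fold 14%, 26% and 24%. It called 0.0642%, 0.0917% and 0.0642% of unchanged genes. A shifted list was found with 0 of 19 other lists called, and a planted word came out at rank 1. Because the simulated genes were uncorrelated, the list result cannot show how often lists of genes that move together are called. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.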

Results

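RNA was measured in LNCaP cells, an androgen-responsive human prostate cancer line, 48 h after siRNA against GATA2, HOXB13 or TFAP2C. The series concerns transcription factors behind enhancer-driven expression in advanced prostate cancer. Each knockdown and the control siRNA (siNT) has 4 libraries, of about 16.3 to 21.9 × 10⁶ fragments each. At that depth 3 fragments in a 2 kb transcript correspond to 0.069 to 0.092 FPKM, and values near this floor carry counting error alone. Between 10570 and 10852 genes reached 1 FPKM in each library. The first principal component (44.1% of the variance) set the siHOXB13 libraries, at 35.2 to 42, apart from all others, and the second (25.8%) set siGATA2 apart, at −33.2 to −24.6. Values are mean ± SD in FPKM (n = 4), and fold changes are differences of mean log2(FPKM + 1), so they understate changes of low genes.

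HOXB13, a homeobox factor of the prostate, fell under its own siRNA from 76.4 ± 4.0 to 14.9 ± 1.51 FPKM (log2 fold change −2.29, SE 0.07, limma adjusted p = 9.7e-14), keeping 19.5%. TFAP2C, which encodes AP-2γ, fell from 8.72 ± 0.783 to 0.681 ± 0.0555 FPKM under its siRNA (−2.53, SE 0.11, adjusted p = 4.3e-10), keeping 7.81%. GATA2, a zinc finger factor, fell far less, from 64.0 ± 2.52 to 47.3 ± 1.56 FPKM under siGATA2 (−0.43, SE 0.05, adjusted p = 7e-06), keeping 73.9%. The factors also moved under each other's siRNA: in siHOXB13, GATA2 fell to 44.7 ± 2.34 FPKM (−0.51, adjusted p = 4.8e-07) and TFAP2C to 4.59 ± 0.937 FPKM (−0.81, adjusted p = 1.1e-05). HOXB13 rose in siGATA2 to 92.4 ± 5.61 FPKM (0.27, adjusted p = 0.0034) and stood at 84.4 ± 3.38 FPKM in siTFAP2C (adjusted p = 0.23). TFAP2C stood at 9.66 ± 1.23 FPKM in siGATA2 (adjusted p = 0.36), and GATA2 at 64.7 ± 3.69 FPKM in siTFAP2C (adjusted p = 0.92).

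**Figure D1:**
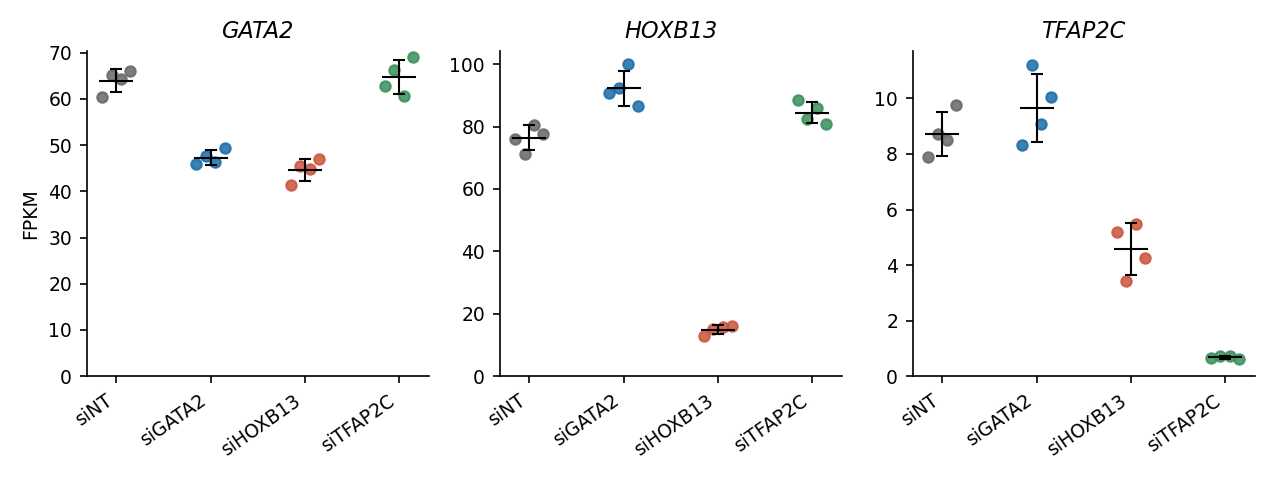
FPKM (vertical axis, from 0) of GATA2, HOXB13 and TFAP2C, with a panel per gene and the 4 siRNA groups along the horizontal axis; points are libraries, and lines with bars are mean ± SD. HOXB13 lies at 14.9 FPKM in siHOXB13 against 76.4 FPKM in siNT, while GATA2 in siGATA2 stays at 47.3 FPKM.

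Most androgen-induced genes fell in siGATA2. KLK3, which encodes PSA, fell from 870 ± 41.7 to 90.4 ± 19.5 FPKM (−3.28, SE 0.12, limma adjusted p = 3e-12), keeping 10.4%. Its neighbour KLK2, whose reads KLK3 may share, fell from 25.8 ± 4.15 to 2.27 ± 0.915 FPKM (−3.07, adjusted p = 7.5e-10). FKBP5, which encodes a co-chaperone, fell from 38.8 ± 6.26 to 20.7 ± 2.89 FPKM (−0.87, adjusted p = 0.0001). TMPRSS2, a membrane protease, fell from 52.9 ± 1.5 to 39.2 ± 2.87 FPKM (−0.42, adjusted p = 5.4e-05).

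After KLK3 and KLK2, the largest falls in siGATA2 were C19orf48 (186 ± 4.62 to 30.3 ± 3.11 FPKM, −2.58), BZW2 (54.3 ± 3.09 to 10.4 ± 2.4 FPKM, −2.3) and the mitochondrial ribosomal protein gene MRPL17 (30.1 ± 1.1 to 5.54 ± 0.423 FPKM, −2.25). The histone chaperone ASF1B fell from 43.7 ± 4.91 to 8.77 ± 2.33 FPKM (−2.22). ZNF385B fell from 12.1 ± 2.42 to 1.9 ± 0.677 FPKM (−2.19) and ARHGDIA from 221 ± 10.5 to 50.5 ± 11.7 FPKM (−2.14). The largest limma adjusted p among these 6 was 2.7e-08. The largest rises were TNFRSF12A, the TWEAK receptor (10.4 ± 3.83 to 44.0 ± 5.3 FPKM, 2.03, adjusted p = 9.9e-07), and SLC51A, a subunit of a bile acid and steroid transporter (0.863 ± 0.482 to 6.37 ± 1.29 FPKM, 2.0, adjusted p = 1.4e-07). Clusterin (CLU) rose from 8.33 ± 2.76 to 32.1 ± 3.16 FPKM (1.87, adjusted p = 4.9e-08). FAM198B rose from 22 ± 4.15 to 74.1 ± 7.68 FPKM (1.72, adjusted p = 4.1e-09) and PIK3IP1, an inhibitor of PI3K, from 2.48 ± 1.21 to 9.76 ± 0.815 FPKM (1.69, adjusted p = 2e-06). The retinol-binding gene RBP5 rose from 0.771 ± 0.234 to 5.69 ± 2.45 FPKM (1.85, adjusted p = 7.4e-06) and the small heat shock gene CRYAB from 1.06 ± 0.368 to 6.06 ± 2.34 FPKM (1.73, adjusted p = 6.1e-05). ID1 rose from 21.9 ± 15.1 to 67.0 ± 27.6 FPKM (1.77, SE 0.67, adjusted p = 0.044), a call lost without siGATA2 replicate 2 (0.0982) and without 4 other libraries in turn.

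Of 31 androgen-induced genes, 22 fell in siGATA2, 3 rose and 6 did not pass; adjusted over the list alone 23 fell and 5 rose. The list moved down (median −0.46, camera adjusted p = 6.7e-07, adjusted p = 0.24 with an estimated correlation). PPAP2A, a lipid phosphatase gene, fell from 140 ± 2.1 to 56.6 ± 3.53 FPKM (−1.3) and KLK4 from 26.5 ± 1.08 to 9.23 ± 1.03 FPKM (−1.43). Of 10 androgen-repressed genes 5 fell as well and 1 rose (the same adjusted over the list alone; median −0.38, camera adjusted p = 0.25). UGT2B17, a glucuronosyltransferase with close relatives, fell from 72.3 ± 7.49 to 33.8 ± 4.53 FPKM (−1.08, adjusted p = 1e-06).

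Proliferation genes fell with GATA2 siRNA: 35 of 37 cell cycle genes fell, none rose and 2 did not pass (35 adjusted over the list alone; median −0.53, camera adjusted p = 1.8e-13, adjusted p = 0.2 with an estimated correlation). BIRC5, which encodes survivin, fell from 47.7 ± 1.96 to 26.6 ± 0.786 FPKM (−0.82). The replication genes fell too, MCM6 from 37.8 ± 0.536 to 20.5 ± 1.83 (−0.86), PCNA from 178 ± 7.78 to 103 ± 6.52 (−0.79) and CDT1 from 25.5 ± 0.767 to 11.8 ± 2.04 FPKM (−1.06). Cholesterol and fatty acid synthesis moved down, with 16 of 26 genes fallen, 1 risen and 9 not past (16 and 2 adjusted over the list alone; median −0.26, camera adjusted p = 0.0029, adjusted p = 0.35 with an estimated correlation). Its master regulator SREBF2 fell from 76.2 ± 3.35 to 30.5 ± 4.05 FPKM (−1.3). ACLY, which makes acetyl-CoA for both pathways, fell from 105 ± 5.16 to 75.4 ± 5.65 FPKM (−0.48).

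Of 6 genes that AP-2γ drives in other cells 5 rose and 1 fell in siGATA2 (the same adjusted over the list alone; median 0.51, camera adjusted p = 0.038, adjusted p = 0.31 with an estimated correlation), a list call lost without siGATA2 replicate 3 (0.056). ERBB2 rose from 29.8 ± 2.07 to 81.7 ± 6.31 FPKM (1.42, limma adjusted p = 4.2e-09). KRT8 rose from 161 ± 7.12 to 265 ± 9.78 (0.72) and CDH1, E-cadherin, from 125 ± 2.32 to 170 ± 10.6 FPKM (0.43), while EGFR fell from 6.46 ± 0.948 to 2.69 ± 0.541 FPKM (−1.02). Of 12 luminal markers 8 rose, 1 fell, KLK3, and 3 did not pass (8 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 0.019, adjusted p = 0.28 with an estimated correlation). FOLH1, which encodes PSMA, rose from 163 ± 6.27 to 250 ± 11.2 FPKM (0.62) and CLDN7 from 144 ± 10.1 to 202 ± 5.87 FPKM (0.49). In total 2742 genes rose and 2625 fell in siGATA2, 48.3% of those tested, and 178 of the falls had a log2 fold change of −1 or below. The siGATA2 and siNT libraries did not overlap in 43.2% of genes, against 2.86% by chance.

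Androgen-induced genes went both ways in siHOXB13. KLK3 rose to 1280 ± 126 FPKM (0.55, limma adjusted p = 0.00083) and KLK2 to 44.0 ± 5.96 FPKM (0.75, adjusted p = 0.0014). KLK4 rose to 53.9 ± 3.0 FPKM (0.99, adjusted p = 7.3e-09). TMPRSS2 fell to 19.1 ± 0.902 FPKM (−1.42, adjusted p = 1.6e-11) and STEAP2, a metalloreductase gene, from 58.6 ± 2.02 to 29.8 ± 2.92 FPKM (−0.96, adjusted p = 2.2e-09). FKBP5 stood at 44.2 ± 10.5 FPKM (0.17, adjusted p = 0.33). In all, 12 androgen-induced genes rose, 15 fell and 4 did not pass (14 and 15 adjusted over the list alone), and the list did not pass (median −0.11, or 0.02 after quantile normalization; camera adjusted p = 0.78).

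In siHOXB13 the lipogenic gene THRSP rose from 0.504 ± 0.121 to 17.8 ± 6.09 FPKM (3.59, limma adjusted p = 1e-11). The glucuronosyltransferase gene UGT2B11 rose from 38.0 ± 2.79 to 457 ± 45.8 FPKM (3.55), UGT2B28 from 14.6 ± 1.83 to 110 ± 8.21 (2.83) and UGT2B10 from 7.32 ± 0.541 to 45.7 ± 7.51 FPKM (2.48), though reads may be assigned between these paralogs. GJB1, connexin 32, rose from 1.03 ± 0.128 to 14.7 ± 3.36 FPKM (2.92), TM4SF1 from 8.91 ± 1.11 to 53.2 ± 10.2 (2.44) and AZGP1, a secreted zinc glycoprotein, from 2.66 ± 0.623 to 16.8 ± 2.27 FPKM (2.29). The largest falls were TMEFF2, a membrane protein of prostate and brain (46.9 ± 4.62 to 1.68 ± 0.509 FPKM, −4.18, SE 0.12, adjusted p = 5.8e-14), and FAM65B (43.6 ± 5.61 to 2.53 ± 0.857 FPKM, −3.69). The zinc transporter SLC30A4 fell from 19.2 ± 0.419 to 1.2 ± 0.118 FPKM (−3.2) and the protease MMP16 from 17.9 ± 1.94 to 1.26 ± 0.808 FPKM (−3.13). The potassium channel gene KCNN2 fell from 15.9 ± 2.09 to 1.23 ± 0.308 FPKM (−2.92) and the secreted SPON2 from 408 ± 29.1 to 66.1 ± 11.9 FPKM (−2.62). CAMK2N1, an inhibitor of CaM kinase II, fell from 7.55 ± 0.711 to 0.396 ± 0.107 (−2.61) and DGKH from 22.1 ± 3.06 to 2.89 ± 0.182 FPKM (−2.56).

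All 37 cell cycle genes fell in siHOXB13, also adjusted over the list alone (median −1.28, camera adjusted p = 4.3e-23, adjusted p = 0.11 with an estimated correlation). KIF20A fell from 29.8 ± 0.812 to 7.93 ± 0.723 FPKM (−1.79) and thymidylate synthase (TYMS) from 117 ± 4.83 to 37.5 ± 4.1 FPKM (−1.62). CDC20 fell from 105 ± 2.9 to 45.7 ± 2.61 (−1.18) and TPX2 from 48.2 ± 2.25 to 13.3 ± 1.89 FPKM (−1.79). Cholesterol and fatty acid synthesis rose, opposite to siGATA2: 18 of 26 genes rose, 4 fell and 4 did not pass (18 and 4 adjusted over the list alone; median 0.43, camera adjusted p = 2.8e-05, adjusted p = 0.24 with an estimated correlation). FASN rose from 204 ± 37.8 to 625 ± 83.8 FPKM (1.62), FDFT1 from 174 ± 12.3 to 484 ± 61.1 (1.46), HMGCS1 from 26.2 ± 0.989 to 47.4 ± 2.9 (0.83) and MVD from 15.2 ± 0.794 to 25.1 ± 2.32 FPKM (0.68). Steroid metabolism and glucuronidation genes rose in 7 of 15 cases, with 1 fallen and 7 not past (8 and 1 adjusted over the list alone; median 0.36, camera adjusted p = 0.00072, adjusted p = 0.15 with an estimated correlation). UGT2B15 rose from 73.3 ± 11.1 to 326 ± 80.6 FPKM (2.12, adjusted p = 2.8e-08).

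The genes that AP-2γ drives in other cells rose in siHOXB13, 4 of 6 with none fallen (4 adjusted over the list alone; median 0.59, camera adjusted p = 0.005, adjusted p = 0.22 with an estimated correlation). KRT8 rose to 314 ± 7.62 FPKM (0.96), ERBB2 to 76.7 ± 4.85 (1.34), CDH1 to 200 ± 20.7 (0.67) and ERBB3 from 38.9 ± 4.81 to 55.6 ± 4.67 FPKM (0.51, limma adjusted p = 0.00049). Among 18 luminal transcription factors 11 fell, 3 rose and 4 did not pass (11 and 4 adjusted over the list alone; median −0.41, camera adjusted p = 0.11). The siRNA target HOXB13 was among the fallen. ETV1 fell from 101 ± 9.02 to 19.8 ± 5.57 FPKM (−2.33, adjusted p = 3.1e-10) and FOXA1, a pioneer factor, from 80.7 ± 1.08 to 60.7 ± 2.7 FPKM (−0.41, adjusted p = 7.8e-07). SPDEF rose from 38.2 ± 2.17 to 97.7 ± 4.5 FPKM (1.33, adjusted p = 1.4e-11) and CREB3L4 from 33.0 ± 1.23 to 65.1 ± 7.11 FPKM (0.95, adjusted p = 3.5e-09). In total 2568 genes rose and 3255 fell, 52.4% of those tested, and 126 and 517 did so by a log2 fold change of at least 1; the risen share of 44.1% becomes 54.2% after quantile normalization. Libraries did not overlap in 47% of genes, against 2.86% by chance.

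TFAP2C siRNA changed fewer genes than the other siRNAs. KLK2 fell to 8.05 ± 1.32 FPKM (−1.57, limma adjusted p = 1.6e-05). KLK3 fell to 338 ± 12.8 FPKM (−1.36, adjusted p = 1.2e-06). TMPRSS2 fell to 25.7 ± 2.16 (−1.01, adjusted p = 5.1e-08) and FKBP5 to 24.5 ± 1.53 FPKM (−0.63, adjusted p = 0.01). SLC45A3, a prostate transporter gene also called prostein, fell from 38.4 ± 2.12 to 14.0 ± 1.76 FPKM (−1.4, adjusted p = 1e-06) and ABCC4, a drug and nucleotide exporter, from 40.2 ± 1.76 to 24.7 ± 0.725 FPKM (−0.68, adjusted p = 2.6e-07). Of 31 androgen-induced genes 22 fell, none rose and 9 did not pass, and 26 fell adjusted over the list alone. The list moved down (median −0.64, camera adjusted p = 1.7e-27, adjusted p = 0.028 with an estimated correlation), the only list call in any knockdown that an estimated correlation left in place. Androgen-repressed genes moved up, with 6 of 10 risen, 1 fallen and 3 not past (7 risen and 2 fallen adjusted over the list alone; median 0.59, camera adjusted p = 0.005, adjusted p = 0.28 with an estimated correlation). UGT2B17 rose to 121 ± 12.5 FPKM (0.74, adjusted p = 0.00047), UGT2B15 to 139 ± 24.3 (0.91, adjusted p = 0.0033) and dopa decarboxylase (DDC) from 29.2 ± 4.4 to 57.0 ± 9.75 FPKM (0.94, adjusted p = 0.015). The 1 fallen gene was their paralog UGT2B28 (−1.05), and reads may be assigned between UGT2B genes.

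**Figure D2:**
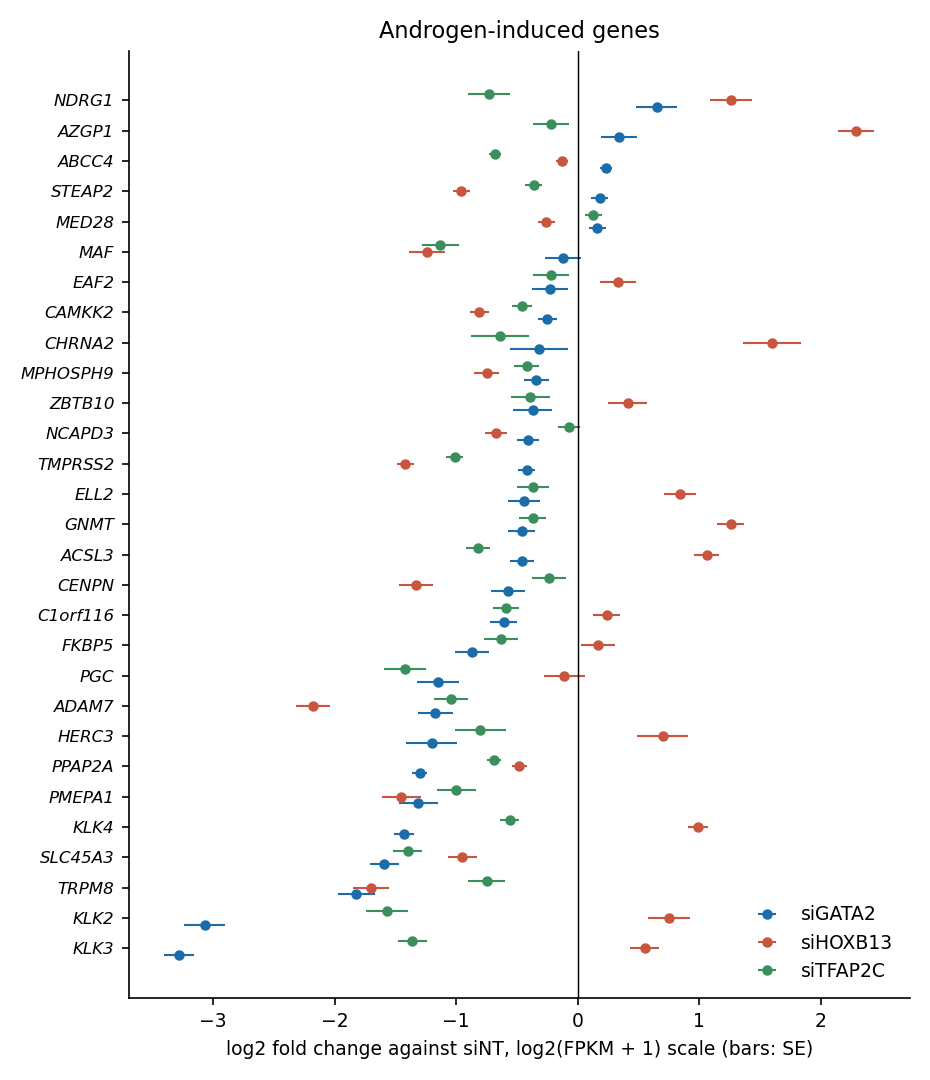
Log2 fold change against siNT ± SE on the log2(FPKM + 1) scale (horizontal axis) of androgen-induced genes (vertical axis), with a point per gene for each knockdown. Of the 31 in the full list, 22 fell in siTFAP2C and none rose, whereas in siHOXB13 12 rose and 15 fell.

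The other large falls in siTFAP2C were the pepsinogen gene PGC (8.61 ± 0.946 to 2.63 ± 0.777 FPKM, −1.42, limma adjusted p = 2.7e-05) and MRFAP1 (238 ± 5.62 to 88.9 ± 14.0 FPKM, −1.42, adjusted p = 7.9e-08). GNB4, a G protein subunit, fell from 20.8 ± 1.03 to 7.78 ± 0.848 FPKM (−1.31, adjusted p = 1.7e-06). Smooth muscle actin (ACTA2) rose from 2.95 ± 1.0 to 12.4 ± 2.38 FPKM (1.78, adjusted p = 1.8e-06), CLU to 27.1 ± 3.02 (1.63), CAMK2N1 to 20.2 ± 3.69 (1.3) and TNFRSF12A to 23.3 ± 7.77 FPKM (1.09, adjusted p = 0.0034). TMSB4X, which has close relatives, rose from 48.5 ± 6.16 to 103 ± 6.82 FPKM (1.08) and SESN3 from 8.69 ± 1.42 to 18.6 ± 2.27 FPKM (1.02). DHRS2 rose from 4.01 ± 1.58 to 8.8 ± 0.249 (1.02, adjusted p = 0.0013) and the tight junction gene CGN from 5.18 ± 0.42 to 11 ± 0.718 FPKM (0.96).

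p53 targets moved up in siTFAP2C: 7 of 22 rose, 1 fell and 14 did not pass (8 and 1 adjusted over the list alone; median 0.2, camera adjusted p = 0.00034, adjusted p = 0.32 with an estimated correlation). TP53INP1 rose from 12.4 ± 1.41 to 21.4 ± 0.773 FPKM (0.75), SESN1 from 20.7 ± 0.532 to 31.1 ± 2.77 (0.56) and BTG2 from 8.24 ± 0.616 to 12.9 ± 1.68 FPKM (0.58, limma adjusted p = 0.002). MDM2, itself a p53 target and its inhibitor, fell from 29.6 ± 2.63 to 20.1 ± 2.74 FPKM (−0.54, adjusted p = 0.0012). Of 37 cell cycle genes 4 fell, 1 rose and 32 did not pass (5 and 2 adjusted over the list alone; median −0.05, camera adjusted p = 0.21). Luminal transcription factors, TFAP2C among them, moved down with 6 of 18 fallen, none risen and 12 not past (9 fallen and 3 risen adjusted over the list alone; median −0.13, camera adjusted p = 0.0053, adjusted p = 0.11 with an estimated correlation). SPDEF fell to 23.5 ± 1.61 FPKM (−0.68, adjusted p = 1.8e-06) and KLF5 from 1.65 ± 0.524 to 0.654 ± 0.185 FPKM (−0.66, adjusted p = 0.0067). Hypoxia genes moved down with 2 of 17 fallen and 15 not past (2 adjusted over the list alone; median −0.19, camera adjusted p = 0.017, adjusted p = 0.62 with an estimated correlation), a call lost without siTFAP2C replicate 2 (0.064). PFKFB3 fell from 8.22 ± 1.31 to 5.09 ± 0.843 FPKM (−0.6, adjusted p = 0.0056). HK2 fell from 16.1 ± 1.11 to 12.4 ± 1.95 FPKM (−0.35, adjusted p = 0.027), a call lost in 6 of the 8 comparisons that leave a library out. In total 383 genes rose and 527 fell, 8.19% of those tested, with 8 and 22 at a log2 fold change of at least 1. Libraries did not overlap in 16.4% of genes, against 2.86% by chance.

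**Figure D3:**
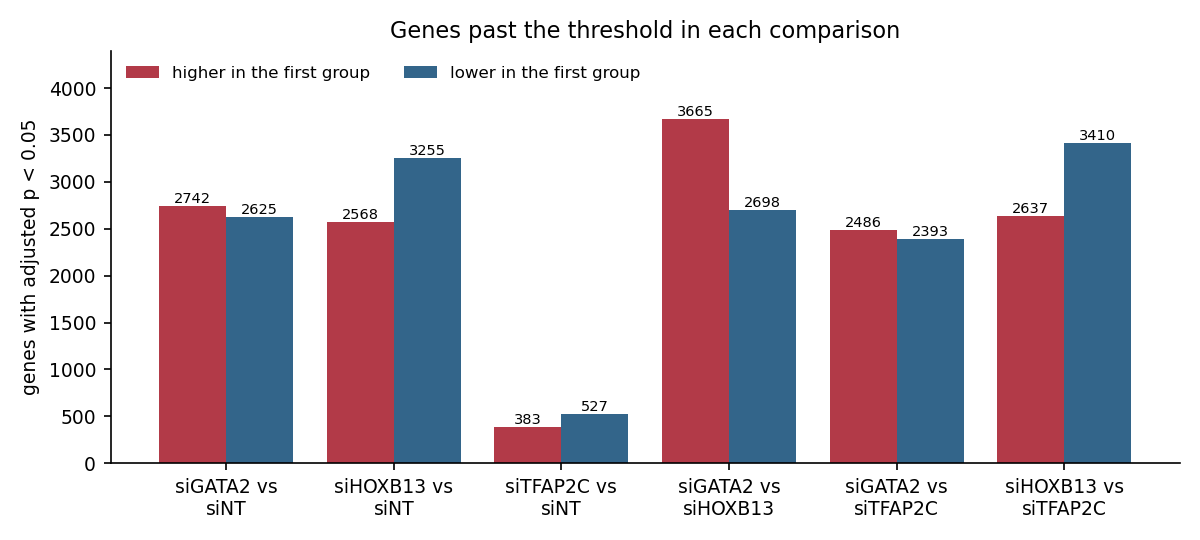
Numbers of genes at adjusted p under 0.05 (vertical axis), higher and lower, in the 3 knockdowns against siNT and the 3 comparisons between knockdowns (horizontal axis); each bar is a count, printed at its end. siTFAP2C has 383 higher and 527 lower genes, against 2742 and 2625 in siGATA2.

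Cytosolic ribosomal protein genes moved up in siTFAP2C, with 2 of 45 risen and 43 not past (1 adjusted over the list alone; median 0.13, camera adjusted p = 8e-07, adjusted p = 0.54 with an estimated correlation), a call lost after quantile normalization (0.43). RPL3 rose from 2220 ± 133 to 2650 ± 144 FPKM (0.26, limma adjusted p = 0.0078), a call lost after quantile normalization (0.12, adjusted p = 0.167), and its many pseudogenes make the value uncertain. In siHOXB13 17 rose and 28 did not pass (14 adjusted over the list alone; median 0.14, camera adjusted p = 0.0029, adjusted p = 0.69 with an estimated correlation). With median-of-ratios scaling 26 rose. After quantile normalization 1 rose and 4 fell, the median was 0 and RPS2 turned from 0.18 (adjusted p = 0.0052) to −0.05. In siGATA2 8 fell and 37 did not pass (5 adjusted over the list alone; median −0.08, camera adjusted p = 0.064). Ribosomal protein genes held 26.6 ± 1.07% of all FPKM in siNT, 25.0 ± 0.443% in siGATA2, 27.5 ± 0.729% in siHOXB13 and 28.3 ± 0.837% in siTFAP2C.

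The remaining lists did not pass, and their counts are given as risen, fallen and not past in siGATA2, siHOXB13 and siTFAP2C in turn, with those adjusted over the list alone beside them only where they differ. Luminal transcription factors in siGATA2 counted 4, 6 and 8 (median −0.09, camera adjusted p = 0.35), and MYC fell there from 80.3 ± 8.82 to 38.1 ± 5.76 FPKM (−1.06). The siRNA target GATA2 was also among the fallen. Androgen-repressed genes in siHOXB13 counted 3, 5 and 2 (4 risen adjusted over the list alone; median −0.06 but mean 0.07, and the test pointed up, 0.83). p53 targets counted 5, 8 and 9 in siGATA2 (median −0.03, 0.49) and 2, 10 and 10 in siHOXB13 (median −0.27, 0.23). Cholesterol and fatty acid synthesis in siTFAP2C counted 1, 3 and 22 (4 fallen adjusted over the list alone; median −0.05, 0.29). Steroid metabolism counted 2, 5 and 8 in siGATA2 (median −0.04, 0.49) and 2, 1 and 12 in siTFAP2C (2 fallen adjusted over the list alone; median −0.05, 0.45). Luminal markers counted 5, 2 and 5 in siHOXB13 (median 0.19, 0.34), where ACPP, the prostatic acid phosphatase gene, fell from 6.28 ± 0.406 to 1.15 ± 0.114 FPKM (−1.76). In siTFAP2C they counted 3, 2 and 7 (5 risen adjusted over the list alone; median 0.1 and test up but mean −0.07, 0.45), and KRT19 fell from 3.78 ± 1.2 to 0.552 ± 0.184 FPKM (−1.59, limma adjusted p = 4e-05). The AP-2γ genes counted 2, 1 and 3 in siTFAP2C (3 risen adjusted over the list alone; median 0.21, 0.094), with KRT8 at 196 ± 8.76 FPKM (0.28, adjusted p = 0.00089) and ERBB2 at 42.9 ± 6.79 FPKM (0.5, adjusted p = 0.0022) both risen.

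Interferon genes (13) counted 3, 4 and 6, then 2, 6 and 5, then 2, 0 and 11 (medians 0.1, −0.27 and 0.07; camera adjusted p = 0.92, 0.49 and 0.26), and in siGATA2 the mean was 0 and the test pointed down. Stress response genes (23) counted 0, 7 and 16, then 7, 4 and 12, then 0, 0 and 23 (medians −0.14, −0.05 and −0.07; 0.34, 0.54 and 0.26). Their mean was 0.01 in siGATA2 and 0.11 in siHOXB13, where the test pointed up and the median became 0.01 after quantile normalization; XBP1 rose there from 113 ± 18.6 to 459 ± 28.4 FPKM (2.03, limma adjusted p = 2.7e-09). Mesenchymal genes (6) counted 2, 4 and 0, then 0, 2 and 4, then 2, 1 and 3 (medians −0.39, −0.07 and 0.16; 0.31, 0.45 and 0.46; 3 risen in siTFAP2C adjusted over the list alone), and the siHOXB13 median became 0.04 after quantile normalization. Fibronectin (FN1) fell in siGATA2 from 40.8 ± 1.15 to 10.4 ± 1.28 FPKM (−1.88). Hypoxia genes counted 2, 3 and 12 in siGATA2 and 5, 3 and 9 in siHOXB13 (medians −0.06 and 0.04; 0.54 and 0.46). MHC class I genes (10) counted 3, 1 and 6, then 0, 7 and 3, then 0, 0 and 10 (medians 0.1, −0.36 and 0.09; 0.78, 0.062 and 0.49; adjusted over the list alone 2 fallen in siGATA2, and 1 risen and 1 fallen in siTFAP2C). TAP2, a peptide transporter gene, fell in siHOXB13 from 15 ± 0.854 to 7.08 ± 1.18 FPKM (−1.0).

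HOXB and PRAC genes (3) counted 1, 0 and 2, then 0, 2 and 1, then 0, 0 and 3 (medians 0.27, −0.35 and 0.13; camera adjusted p = 0.35, 0.19 and 0.38). The siRNA target HOXB13 was 1 of the 2 fallen in siHOXB13. The GATA and AP-2 families (4) counted 0, 1 and 3, then 0, 3 and 1, then 0, 1 and 3 (medians −0.13, −0.41 and 0.11; 0.7, 0.11 and 0.45), and in siTFAP2C the mean was −0.52 and the test pointed down. The 1 fallen gene was the siRNA target itself, GATA2 in siGATA2 and TFAP2C in siTFAP2C (−2.53). None of 13 mitochondrially encoded genes passed in any knockdown (medians 0.19, 0.28 and 0.07, the last −0.01 after quantile normalization; 0.45, 0.22 and 0.46). Metallothioneins (4) counted 1, 0 and 3, then 0, 0 and 4 in both others (medians 0.25, −0.08 and −0.03; 0.29, 0.92 and 0.78), and in siHOXB13 the test pointed up. Housekeeping genes (12) counted 2, 2 and 8, then 3, 5 and 4, then 1, 1 and 10 (medians 0, −0.08 and 0.07; 0.93, 0.75 and 0.75); the siGATA2 median became −0.02 with median-of-ratios scaling. ACTB rose in siGATA2 from 1080 ± 37.6 to 1460 ± 36.5 FPKM (0.43, limma adjusted p = 6.3e-07). Marker lists with under 3 tested genes had no list test: the basal marker ITGB4 rose from 1.02 ± 0.35 to 2.41 ± 0.168 FPKM in siGATA2 and 2.1 ± 0.506 FPKM in siTFAP2C. The macrophage marker CD68 rose from 0.833 ± 0.183 to 2.18 ± 0.154 FPKM in siGATA2 and 1.44 ± 0.256 FPKM in siHOXB13. The neuronal tubulin TUBB3 rose in siTFAP2C from 7.22 ± 1.9 to 12.4 ± 3.7 FPKM (adjusted p = 0.041), and the fibroblast collagen COL1A1, at 4.18 ± 0.678 FPKM in siNT, did not pass in any knockdown.

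**Figure D4:**
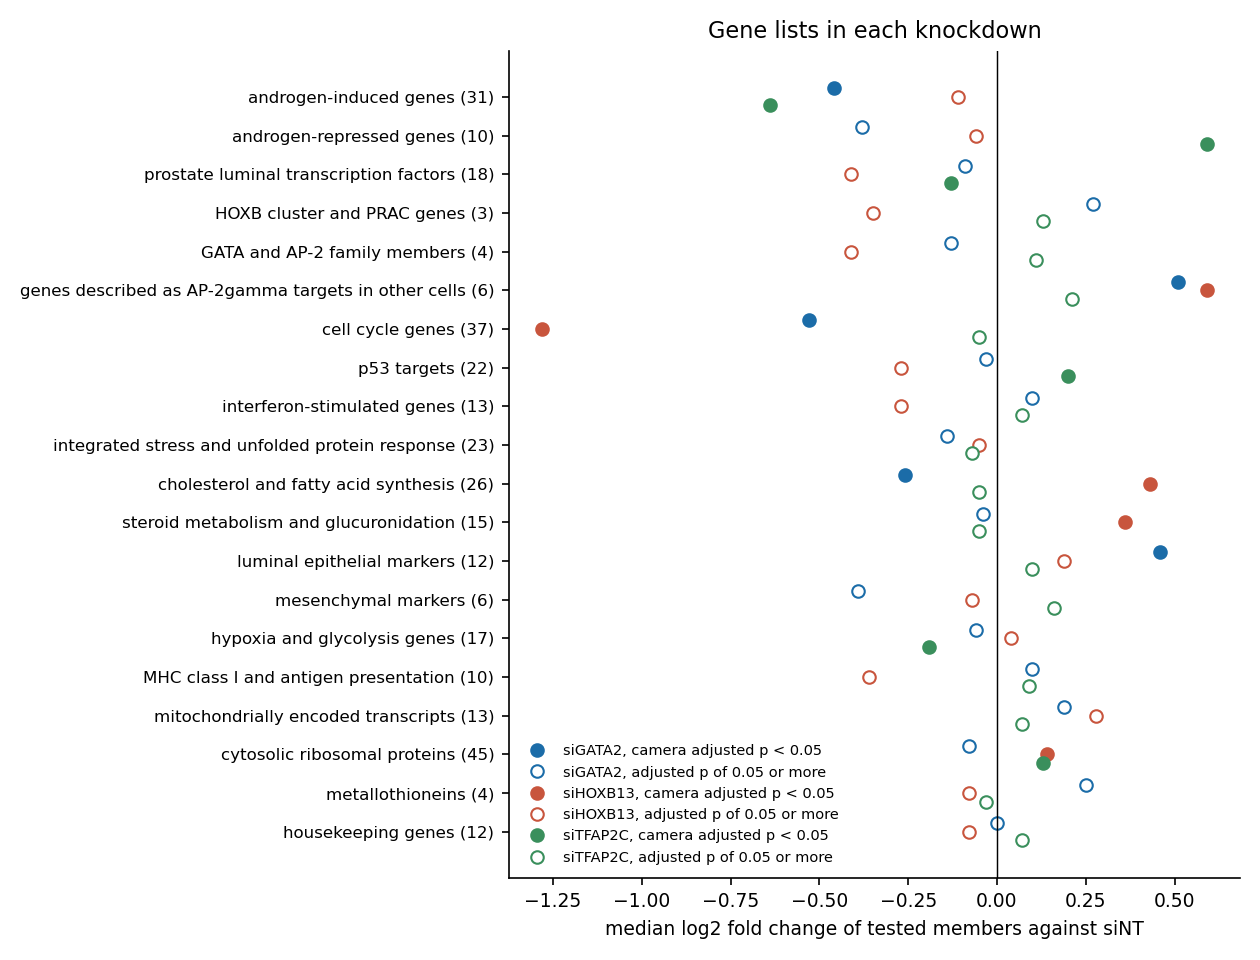
Median log2 fold change against siNT (horizontal axis) of tested gene lists (vertical axis, with numbers of tested genes), a point per knockdown; filled points are lists with camera adjusted p under 0.05 at the preset correlation. Cell cycle genes lie lowest in siHOXB13 (−1.28) and androgen-induced genes lowest in siTFAP2C (−0.64).

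Against the same 4 controls, 112 genes rose and 161 fell in each of the 3 knockdowns, where unrelated lists would share 22 and 36. When no control library served more than 1 comparison, which leaves 1 or 2 controls for each, these counts were 7 to 31 and 14 to 47 over 36 ways of splitting them, against 1 to 3 and 3 to 8 from unrelated lists of those lengths. CLU rose to 32.1, 37.5 and 27.1 FPKM in siGATA2, siHOXB13 and siTFAP2C (1.87, 2.09 and 1.63). GNB4 fell to 4.65 ± 1.02, 5.07 ± 0.73 and 7.78 ± 0.848 FPKM, and SLC45A3 to 12.2 ± 2.26, 19.4 ± 2.54 and 14.0 ± 1.76 FPKM. PMEPA1, an androgen-induced gene, fell from 24.4 ± 6.02 to 9.19 ± 1.67, 8.15 ± 1.19 and 11.6 ± 1.67 FPKM. ADAM7 fell from 6.17 ± 1.0 to 2.18 ± 0.351, 0.584 ± 0.256 and 2.5 ± 0.58 FPKM. Counts of genes called in a pair share the same 4 controls, so each stands beside the number from unrelated lists, then the range of 6 ways of splitting the controls and that of unrelated lists of the split lengths. Simulations of unchanged groups gave 0, but such groups hold almost no calls to share. siGATA2 and siHOXB13 shared 1093 risen genes (634 from unrelated lists; split, 696 to 759 against 383 to 423). They shared 1365 fallen genes (769; split, 996 to 1052 against 505 to 553), and 796 went opposite ways (1410; split, 492 to 604 against 896 to 974). siGATA2 and siTFAP2C shared 243 risen (95; split, 89 to 111 against 26 to 42) and 293 fallen (125; split, 122 to 149 against 49 to 63), with 103 opposite (221; split, 40 to 68 against 78 to 104). siHOXB13 and siTFAP2C shared 148 risen (89; split, 43 to 67 against 27 to 42) and 223 fallen (154; split, 97 to 113 against 63 to 80). In this pair 238 went opposite ways (234; split, 105 to 153, overlapping an unrelated range that starts at 86). That unrelated range ends below the split mean of 117. Opposite genes were thus not fewer than from unrelated lists, so the shared risen and fallen genes of this pair alone do not show a shared response. For the 3 knockdowns together and for each pair, numbers from unrelated lists take every gene as equally likely to be called. Fold changes correlated at 0.353, 0.392 and 0.148 in these pairs, below the 0.492, 0.501 and 0.497 of 20 simulations of unchanged groups with shared controls, while the covariances of 0.072, 0.033 and 0.015 exceeded the simulated 0.007. With split controls the covariances were 0.062 to 0.069, 0.021 to 0.03 and 0.002 to 0.012.

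Set against each other, siGATA2 and siHOXB13 differed most, with 3665 genes higher and 2698 lower in siGATA2 (57.3% of those tested; 48.6% without overlap, 2.86% by chance). The share higher in siGATA2, 57.6%, became 48.8% after quantile normalization, with 3040 higher and 3190 lower. KLK3 was lower in siGATA2 (−3.83, limma adjusted p = 9.9e-14), as were KLK2 (−3.82) and FKBP5 (−1.04, adjusted p = 9.3e-06), while TMPRSS2 was higher (1.0, adjusted p = 1.3e-09). CAMK2N1 rose in siGATA2 to 20 ± 1.8 FPKM and fell in siHOXB13, which made it the largest difference upward (3.91, adjusted p = 2.3e-14). FAM65B (36.4 ± 6.4 FPKM in siGATA2, 3.42), SLC30A4 (21.5 ± 0.758, 3.35) and DGKH (32.6 ± 5.33, 3.1) were also higher there. So was ARG2, arginase 2, at 156 ± 11.1 FPKM in siGATA2, 16.5 ± 1.07 in siHOXB13 and 77.0 ± 9.36 in siNT. UGT2B11 (34.5 ± 7.06 FPKM in siGATA2; −3.7) and UGT2B28 (9.07 ± 1.51; −3.47) were lower in siGATA2. The Hedgehog effector GLI3 rose in siGATA2 from 3.72 ± 1.4 to 9.24 ± 2.08 FPKM (1.16, adjusted p = 0.0026), fell in siHOXB13 to 1.3 ± 0.632 FPKM (−1.02, adjusted p = 0.0055). It stood at 5.68 ± 2.2 FPKM in siTFAP2C (adjusted p = 0.35). The transporter gene SLC16A6 rose in siHOXB13 from 6.56 ± 0.441 to 18.1 ± 2.1 FPKM (1.33) and fell in siGATA2 to 2.01 ± 0.152 (−1.33) and in siTFAP2C to 2.72 ± 0.385 FPKM (−1.03).

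Between siGATA2 and siTFAP2C 2486 genes were higher in siGATA2 and 2393 lower (43.9% of those tested; 39.7% without overlap, 2.86% by chance). KLK3 was lower in siGATA2 (−1.92, limma adjusted p = 2.8e-09), as was KLK2 (−1.5), while TMPRSS2 was higher (0.59) and FKBP5 did not pass (−0.24, adjusted p = 0.19). After TFAP2C itself (2.66), KRT19 (6.5 ± 0.566 FPKM in siGATA2; 2.28), RBP5 (0.763 ± 0.562 in siTFAP2C; 1.9), CRYAB (1.21 ± 1.26 in siTFAP2C; 1.76) and MRFAP1 (271 ± 21.8 in siGATA2; 1.61) were most above siTFAP2C. BZW2 (53.1 ± 2.67 FPKM in siTFAP2C; −2.27), ARHGDIA (232 ± 7.76; −2.21), ASF1B (43.0 ± 2.85; −2.21) and MRPL17 (27.4 ± 2.12; −2.12) were most below it. The integrin gene ITGB1 stood at 22.1 ± 2.32 FPKM in siGATA2 and 105 ± 5.6 FPKM in siTFAP2C (−2.21, adjusted p = 5.8e-13).

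Between siHOXB13 and siTFAP2C 2637 genes were higher in siHOXB13 and 3410 lower (54.4% of those tested; 47.3% without overlap, 2.86% by chance). The share higher in siHOXB13, 43.6%, became 53.4% after quantile normalization, with 3169 higher and 2760 lower. KLK3 (1.91, limma adjusted p = 5.1e-10), KLK2 (2.31) and FKBP5 (0.8, adjusted p = 0.00015) were higher in siHOXB13 and TMPRSS2 lower (−0.41, adjusted p = 4.9e-05). UGT2B11 (28.6 ± 5.15 FPKM in siTFAP2C; 3.96), UGT2B28 (6.57 ± 1.08; 3.88), TM4SF1 (3.85 ± 0.551; 3.47) and THRSP (0.661 ± 0.0745; 3.45) were far above siTFAP2C. CAMK2N1 (−3.91), TMEFF2 (37.0 ± 3.53 FPKM in siTFAP2C; −3.84), MMP16 (22 ± 4.01; −3.4) and SLC30A4 (20.4 ± 0.5; −3.28) were most below it. DDC stood at 4.56 ± 2.35 FPKM in siHOXB13 and 57.0 ± 9.75 in siTFAP2C (−3.47, adjusted p = 1.5e-09).

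Fallen genes shared short 3′ UTR words in each knockdown. In siGATA2 the word CAGGCCT had the lowest t (−12.1, against −4.5 at the lowest of 100 permutations), and 35.6% of the 1678 genes carrying it fell against 21.3% of the others. In siHOXB13 it was GCCTTCT (t = −14, permutations −4.6), with 46.6% of 1459 carriers fallen against 27.1%. In siTFAP2C it was AGCCGAA (t = −6.4, permutations −4.9), with 18.3% of 180 carriers fallen against 4.6%. In the other knockdowns these words had t between −2.1 and 0.6. No word exceeded the highest permuted t in any knockdown. Words below the permutations numbered 24, 10 and 7 in siGATA2, siHOXB13 and siTFAP2C. At least 1 of them was carried by 6798, 7138 and 3051 of 10091 genes, of which 25.8%, 34.1% and 8.0% fell. Among genes without any, 19.3%, 19.8% and 3.4% fell. The siHOXB13 words include TTTTTTA, carried by 4487 genes, and TTTTGTA, carried by 3602, which do not resemble the lead word. Carriers of a word in siHOXB13 are therefore a mixed set. Of cell cycle genes without any such word, 15 of 17 fell in siGATA2, 10 of 10 in siHOXB13 and 4 of 34 in siTFAP2C. In siGATA2 their median was −0.4, against −0.72 for those with a word, of which 20 of 20 fell. The medians without and with a word were −1.21 and −1.29 in siHOXB13, and −0.05 and −0.06 in siTFAP2C. Of androgen-induced genes without a word 3 of 5 fell in siGATA2 and 9 of 15 in siTFAP2C, while in siHOXB13 2 of 8 fell and 5 rose. Of those with a word 18 of 25, 12 of 15 and 12 of 22 fell in siGATA2, siTFAP2C and siHOXB13, and in siHOXB13 the medians were −0.2 with a word and 0.77 without. In siGATA2 they were −0.46 with a word and −1.15 without, and in siTFAP2C −0.63 and −0.64. TMPRSS2 carried 7 of the siGATA2 words, and 22.7% of 1738 other genes with at least as many had as low a fold change. That share was 4.3% for FKBP5, with 4 words, and 0.0% for KLK3 and KLK2, with 2 words each. In siHOXB13 TFAP2C carried 4 words, the lead word among them. Of 1913 other genes with at least as many, 11.3% had as low a fold change. The share was 19.7% of 4839 for GATA2, with 2 words, and 0.1% for HOXB13 itself, also with 2. Whether the falls of TFAP2C and GATA2 there follow from loss of HOXB13 was not tested. The words were picked from these same fold changes, so lower values of carriers are partly built in. Shares and medians with and without any word are not adjusted for UTR length.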

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

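The 3 lead-word tests were fixed before the data were examined; every other test in this part was chosen after the results were seen. One of them, for reads moved between KLK genes, replaced an earlier test, the 9 androgen-induced genes outside the KLK family that rose in siHOXB13.

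The fallen genes share 3′ UTR words, as genes hit through the seed of an siRNA would, with a lowest t of −12.1 in siGATA2, −14 in siHOXB13 and −6.4 in siTFAP2C. Part of each response could therefore be an off-target effect, but the siRNA sequences are not given in the sources used here, so no seed could be compared with these words. Loss of the target itself as the cause of each fall was not tested.

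GATA2 mRNA kept 73.9% in siGATA2 while KLK3 kept 10.4%. Untransfected cells could hold GATA2 up, but they would hold up every other gene too, and 66 genes kept a smaller share than 0.5 of that of GATA2. A swapped library is unlikely, as 4 of 4 siGATA2 libraries lie below every siNT library for both KLK3 and GATA2. The GATA2 3′ UTR itself carried 6 of the words that marked fallen genes in siGATA2. Of 2188 other genes with at least as many, 21.6% had as low a fold change as GATA2 (−0.43). The fall of GATA2 mRNA thus does not stand apart from that of other carriers. Loss of GATA2 protein without a matching mRNA loss, or off-target falls, would both leave this picture. Protein was not analysed here. In siHOXB13, where KLK3 rose, GATA2 mRNA was no higher than in siGATA2. The log2 difference, siGATA2 minus siHOXB13, was 0.082 (exact permutation test, p = 0.114).

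KLK3 and KLK2 rose in siHOXB13 while TMPRSS2 and STEAP2 fell. The scaling of the libraries is an unlikely cause, since the lowest of their log2 fold changes over 3 scalings was 0.48. Reads moved to KLK3 from other KLK genes could not supply the rise, because those 14 genes together held 53.3 FPKM in siNT against a KLK3 gain of 407 FPKM (SD 133). For KLK2, with far lower values, shared reads may still contribute, and 53.3 FPKM is no bar there. A repressive role of HOXB13 at these genes remains possible and was not tested.

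Regrouping the libraries cannot decide whether chance or handling gave such numbers of changed genes. Every other split mixes the 2 groups, so their difference enters the spread and few calls must follow. In each of the 6 comparisons the real split was the 1 of 35 with as many genes past the threshold, and the highest other split gave 2 genes for siGATA2, 1 for siHOXB13 and 6 for siTFAP2C against siNT, and 2 in each comparison of knockdowns. For siTFAP2C against siNT, a split by replicate number reached those 6 genes. Fragments per library were fewer in siGATA2 (16.3 to 17.3 × 10⁶) than in siNT (19 to 21.5 × 10⁶).

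A Dixon test at the 5% level set 1 library apart from the other 3 in 15 of 456 groups (3.3%), against about 23 by chance. These groups came from 110 genes and 4 library measures. For the share of the 10 highest genes, rounding was made finer after a rounded value alone had passed the test. Above their group stood KLK2 in siTFAP2C (10 FPKM, replicate 3), RBP5 in siHOXB13 (1.93, replicate 3), CRYAB in siTFAP2C (3.1, replicate 1), MRPL17 in siTFAP2C (30.6, replicate 1), CDT1 in siHOXB13 (10.1, replicate 3) and ETV1 in siGATA2 (153, replicate 1). So did ERBB3 in siGATA2 (71.4, replicate 3), BTG2 in siHOXB13 (5.04, replicate 4) and PFKFB3 in siNT (10.2, replicate 3) and in siGATA2 (4.2, replicate 3). Below their group stood CDT1 in siNT (24.3, replicate 1), ERBB2 in siHOXB13 (69.5, replicate 4), TYMS in siTFAP2C (95.4, replicate 3), ADAM7 in siGATA2 (1.65, replicate 1) and HK2 in siHOXB13 (19.5, replicate 4).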

How the results depend on the processing

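Median-of-ratios factors for genes, quantile normalization for lists and the control split for all 3 knockdowns were chosen after the data were seen; the other settings were fixed before. The planned Wald test on counts was not run because the values are FPKM. Quantile normalization, upper quartile factors, no low-value filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 10, fitting only the 2 groups and a replicate block left all counts of changed genes within 1.5-fold. Testing fold changes against 0.58 left 107 risen and 215 fallen genes in siGATA2, 174 and 649 in siHOXB13, and 3 and 17 in siTFAP2C. Between knockdowns it left 564 and 324 (siGATA2 minus siHOXB13), 80 and 162 (siGATA2 minus siTFAP2C), and 226 and 650 (siHOXB13 minus siTFAP2C). GATA2 in siGATA2 (−0.427) did not pass that test. At adjusted p under 0.01, siTFAP2C kept 155 risen and 274 fallen genes. RPS2 in siHOXB13 reversed to −0.054 after quantile normalization. Of 216 single-gene results, 66 were lost against 0.58, 8 at 0.01, 4 after quantile normalization, and 4 with only the 2 groups, and calls were lost 27 times over all comparisons that left a library out. Leaving a library out, siTFAP2C had 240 (without siNT replicate 1) to 315 risen and 351 (without siTFAP2C replicate 1) to 454 fallen genes. For lists, an estimated correlation left 0 up and 0 down in siGATA2, 0 and 0 in siHOXB13, and 0 up and 1 down in siTFAP2C, while fry gave 4 up and 8 down in siGATA2, 11 down in siHOXB13 and 6 up in siTFAP2C. With a replicate block 1 list was up in siGATA2, where the AP-2γ genes lost their call (0.059) and luminal markers did not (0.021), and 2 down in siHOXB13. With a library left out, 1 (without siGATA2 replicate 3) to 2 lists were up in siGATA2, and 1 to 2 down in siHOXB13 (2 without siNT replicate 2 or siHOXB13 replicate 3). Shared calls at 0.01 were 683 risen and 443 opposite for siGATA2 and siHOXB13, 100 risen, 136 fallen and 42 opposite for siGATA2 and siTFAP2C, and 57, 103 and 108 for siHOXB13 and siTFAP2C. With the controls split, the mean was 101 risen, 132 fallen and 47 opposite for siGATA2 and siTFAP2C, and 54, 106 and 117 for siHOXB13 and siTFAP2C. With them split 2, 1 and 1, a mean of 16 genes rose and 27 fell in all 3 knockdowns. Replicate numbers were not treated as pairs, because the rule fixed before asked that every pair correlate above 0.1: 19 of 24 correlations of same-numbered libraries over 2000 genes exceeded 0.1 (−0.158 to 0.564, median 0.272), and 8 of 16 libraries were closest to their own number. With 500 genes 18 pairs exceeded it and 12 libraries were closest to their own number, with 5000 genes 19 and 9. On the third principal component (5.67% of the variance) replicates 1 and 3 lie above 2 and 4 in every group. A replicate block gave 2967 risen and 2786 fallen genes in siGATA2, 2764 and 3427 in siHOXB13, and 567 and 701 in siTFAP2C. It added 5 single-gene calls, among them FKBP5 in siGATA2 minus siTFAP2C (adjusted p = 0.035) and ARG2 in siTFAP2C (0.00795).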

Other observations

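All tests of gene families in this part, 120 over 20 families, were chosen after the results were seen. Families were taken by the start of the gene symbol, which brings in a few genes that are not members by function. The Fisher tests count genes as independent. Members of a family may move together, so these p-values may be too small. In siHOXB13 some families rose more often than other genes, though most such calls depend on the scaling. Of 38 genes named after respiratory complex I 20 rose and none fell (Fisher test, adjusted p = 0.0011), among them NDUFC2 from 126 ± 8.56 to 244 ± 17.8 FPKM (0.95, limma adjusted p = 2e-09) and NDUFV1 from 127 ± 5.69 to 209 ± 13.9 FPKM (0.71, adjusted p = 2e-07). After quantile normalization 16 rose and the family did not pass (0.19). Of 18 cytosolic aminoacyl-tRNA synthetase genes 12 rose and 1 fell (adjusted p = 0.001, also lost after quantile normalization), with HARS rising from 46.7 ± 1.22 to 69.9 ± 2.57 FPKM (0.57), SARS from 117 ± 4.68 to 170 ± 9.7 FPKM (0.53) and AARS falling from 185 ± 3.56 to 117 ± 7.52 FPKM (−0.66). Vacuolar ATPase genes rose in 11 of 17 cases and fell in 3 (adjusted p = 0.0024; 0.014 after quantile normalization). Of 36 genes with proteasome symbols 16 rose and 1, which is not a subunit, fell (adjusted p = 0.023, lost after quantile normalization). Genes with EIF symbols (0.059), a mixed set of translation initiation factors, their inhibitors and kinases, did not pass there, nor did chaperonin subunits (0.65) or genes with HSP symbols (1).

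In siGATA2 20 of 41 histone genes rose and none fell (48.8% against 24.6% of the other tested genes; adjusted p = 0.0062). HIST2H2BE rose from 6.23 ± 1.53 to 21.9 ± 3.38 FPKM (1.67, limma adjusted p = 7.8e-07) and HIST1H2AC from 12.2 ± 3.57 to 34.7 ± 4.52 FPKM (1.46, adjusted p = 2.3e-05). The rise of HIST2H2BE was not confined to siGATA2, as it reached 18.3 ± 1.05 FPKM in siHOXB13 (1.44, limma adjusted p = 2.1e-06). Most histone mRNAs lack a polyA tail and the genes share sequence, so these values are uncertain. Zinc finger genes passed less often in siGATA2 than other genes in both directions: 36 of 401 fell (8.98% against 24.2%; adjusted p = 5.5e-13) and 75 rose (18.7% against 24.9%; adjusted p = 0.023). In siHOXB13 24 of them rose and 113 fell (Fisher test, adjusted p = 4e-19 for few rising). After quantile normalization 54 rose and 63 fell. The Fisher tests did not match families and other genes for expression, and the log2(FPKM + 1) scale understates changes of genes at low values. Whether low expression accounts for the fewer calls among zinc finger genes was not tested.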
